A study of Mus musculus with 4 samples.

How the data were processed

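Islet RNA of newborn mice was sequenced in 4 libraries, 2 labelled Mettl3/14nKO and 2 wild-type, and groups and replicate numbers were taken from the sample labels. Per the labels, ribosomal RNA was removed from total RNA, a directional kit was used, and fragments were read from both ends. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, Cuffdiff, Cufflinks and the genome build mm10; the annotation release, filters and strand setting are not given in the sources used here. Genes that overlap a neighbour or an antisense gene may therefore hold fragments of either.

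The deposited table has 22564 genes, all of them protein-coding, with 22481 symbols, of which 79 stand for several genes. It gives FPKM (fragments per kilobase of transcript, scaled to library size) as deposited by the authors, per the file headers. The estimated counts deposited by the authors, under a header of counts, are not whole. Within each library 92.2 to 93.2% of the values above 0 lie within 0.01 of a whole multiple of 1 step, which was 0.968 and 1.33 for Mettl3/14nKO replicates 1 and 2 and 0.982 and 0.835 for wild-type replicates 1 and 2. These estimated counts were divided by the library's step and rounded, which gave the fragments used for depth, for count models and for CPM (fragments scaled to the library total). The deposited Length column equals the end minus the start of each locus, other than a transcript length, and entered no test. Of the gene identifiers 96.8% were found in the GENCODE annotation of mm10, which supplied coordinates and mRNA features.

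The groups, the test, the named-gene rule, 29 gene lists and most alternatives were fixed before the data were examined. The design assumed FPKM, so the main test was limma 3.58.1 in R 4.3.3 with an intensity trend, on log2(FPKM + 1), for genes with a mean FPKM of at least 1 and with genes of 1 symbol summed. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05, and fold changes on this scale understate the change of low genes. The table also held estimated counts, so DESeq2 1.42.0 was run as planned and edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr) was added after the data were seen. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists, with camera at an estimated correlation and with fry. With an estimated correlation no list passed (adjusted p of 0.738 or more), and with fry, which asks whether a list's genes move 1 way on balance, no list passed either (0.152 or more). Fry's mixed test, which asks whether a list's genes change in either direction, called 14 of the 29 lists (smallest adjusted p 0.00803), and neither fry test compares a list with other genes. A list needed 3 tested members. Unless another setting is named, camera values cover the members that limma tested, while counts of members cover those that edgeR tested. These sets can differ in size, with 11 against 4 acinar markers and 6 against 3 erythroid markers.

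The rule for named genes took Mettl3 and Mettl14, the 10 strongest limma changes in each direction with a mean of at least 5 FPKM in the higher group and no overlap between groups (or, as happened, the next by smallest p), 12 fixed islet genes, and up to 4 members of each list by smallest limma p. Other genes are said to have been chosen after their values were seen. Some genes that the rule or a count would name are not reported here.

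The scripts were tested on simulated fragments with 100 genes changed at each size. For the comparison of Mettl3/14nKO with wild-type, limma recovered 27% of 2-fold and 93% of 4-fold changes over 10807 genes, edgeR 61% and 100% over 10642 genes, and DESeq2 30% and 90% over 10956 genes. Unchanged genes called numbered 3, 10 and 1. The simulated spread was edgeR's own, and each gene had the same FPKM per fragment in every library. In the deposited table the log2 of that value had an SD above 0.25 in 21.5% of genes. Limma's rates may therefore be lower on the deposited FPKM. Camera called 0 of 20 simulated lists of 25 unchanged genes. Genes were simulated independently of each other, while the correlation estimated for the mesenchymal and stellate list was 0.82. That rate therefore does not hold for lists of correlated genes. In all, 30 settings were fitted, with other pseudocounts, filters, scalings, a replicate block, tests and libraries left out in turn. Limma on CPM, limma on the genes that edgeR tests, 4 further gene lists and the pathways of the deposited annotation were added after the data were seen. No library was left out of the main test, and numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for tables and intervals.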

Results

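Transcripts were measured by RNA sequencing in pancreatic islets of newborn mice (postnatal day 0, strain 129sv), the hormone-secreting cell clusters of the pancreas. Of the 4 libraries, 2 came from mice labelled Mettl3/14nKO and 2 from wild-type mice. Mettl3 and Mettl14 are the catalytic and the RNA-binding subunit of the enzyme that places the m6A mark (N6-methyladenosine) on RNA, and the series was made to examine RNA modification in these islets. The table holds transcript levels of 22564 protein-coding genes and no measurement of methylation. The Mettl3/14nKO libraries held 1216493 and 744008 estimated fragments in genes, and the wild-type libraries 1255528 and 1617415, which is shallow for whole-transcriptome data. At least 10 fragments were counted for 10857 and 9355 genes in the Mettl3/14nKO libraries and for 10698 and 11322 in the wild-type libraries. The labels do not say that the libraries of a group came from separate animals or litters, so p-values measure only the spread between these samples, which may be technical. Replicates differed by more than counting noise (chi-square per degree of freedom 2.30 within Mettl3/14nKO and 2.29 within wild-type), so neither pair was treated as repeat deposits of 1 library, which does not show that the samples were biologically separate.

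The targeted genes were lower in the Mettl3/14nKO libraries in FPKM, but neither passed a test. On that scale the median log2 fold change of all genes was also negative (-0.21). In fragments the groups overlapped for Mettl3, with more in Mettl3/14nKO replicate 1 than in the slightly deeper wild-type replicate 1. Mettl3 (ENSMUSG00000022160, mm10 chromosome 14:52294841-52305128) stood at 6.95 and 5.86 FPKM in Mettl3/14nKO and at 8.40 and 14.5 FPKM in wild-type islets, from 30 and 9 against 20 and 47 fragments. Its log2 fold change was -0.71 (SE 0.32) on the log2(FPKM + 1) scale with limma (adjusted p = 0.434) and -0.25 (SE 0.40) with edgeR (adjusted p = 0.849). Mettl14 (ENSMUSG00000028114, chromosome 3:123368297-123386108) stood at 3.75 and 2.66 against 5.06 and 7.55 FPKM, from 24 and 12 against 32 and 54 fragments. Its log2 fold change was -0.79 (SE 0.33, adjusted p = 0.406) with limma and -0.71 (SE 0.32, adjusted p = 0.308) with edgeR. Levels summed over a gene do not test a deletion of single exons, and which exons were targeted is not given in the sources used here. Transcript loss was therefore not detectable for either gene at this depth, and the labels were not checked by it. Of the 8 tested m6A writers and adaptors and the 11 readers and erasers, 0 passed with limma or edgeR, and 0 when adjusted over the list alone. The writers Rbm15b and Mettl16 had edgeR log2 fold changes of -0.13 and -0.51, and the readers Igf2bp2 and Ythdf2 of -0.18 and -0.31 (adjusted p = 0.321 for the writers and 0.759 for the readers with camera).

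Between the genotypes, transcripts of the insulin genes, of endothelial cells and of the interferon response were lower in Mettl3/14nKO islets, and transcripts of leukocytes and connective-tissue cells were higher. Ucn3, a peptide hormone of maturing beta cells, was higher. How many genes passed depended on the test. The planned test, limma on log2(FPKM + 1), called 0 of 12213 genes in either direction at an adjusted p of 0.05, with 1477 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0709. On the estimated fragments behind the same table, edgeR called 230 genes higher and 176 lower of 10956, and DESeq2 92 higher and 50 lower. The edgeR fit was chosen after the data were seen, and "rose" and "fell" refer to its adjusted p under 0.05, not to limma's. Of the 396 edgeR calls that limma also tested, 393 had the same sign with limma and 292 an unadjusted limma p under 0.05, and 136 of the edgeR calls were also DESeq2 calls. Among edgeR calls named here, DESeq2 did not call Iapp, Ppy, Pyy, Pcsk1, S100a8, C1qb, Col1a1, Arhgdib, Lmo4, Isg15, Oasl2, Chac1, Ern1, Dusp1, Nr4a1, Vil1, Stfa2, Ngp, Pglyrp1, Cacna1c, Ccng1, Cdh19, Rpl11, Rplp1, Rpl4 and Rpl19, with adjusted p of 0.0521 to 0.652. The median log2 fold change of all genes was -0.21 in the deposited FPKM and 0.00 with edgeR, whose changes are thus relative to the typical gene.

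**Figure D1:**
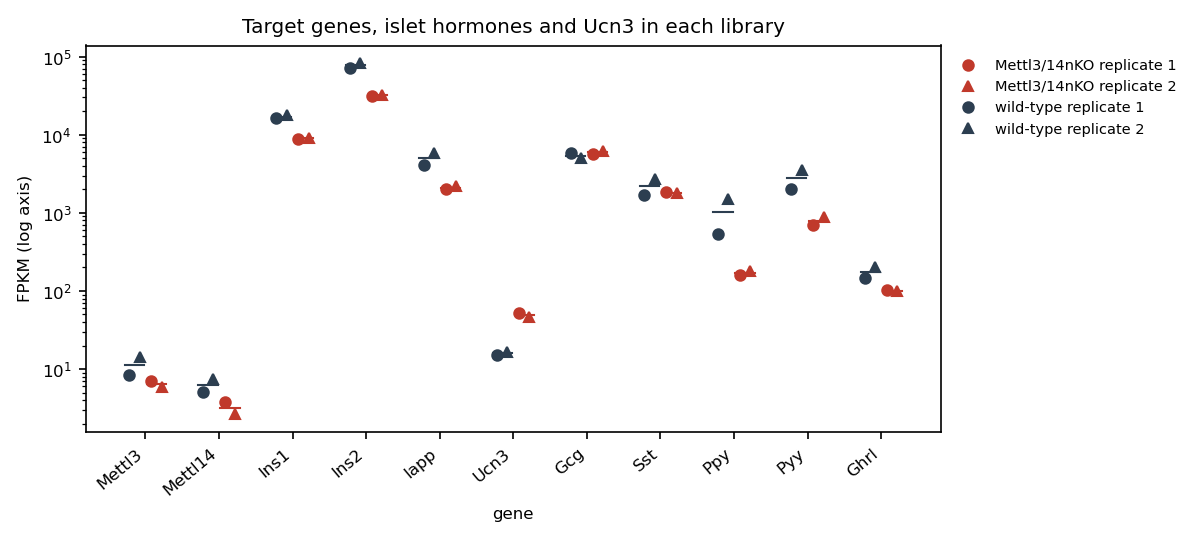
FPKM of Mettl3, Mettl14, the islet hormone genes and Ucn3 in each library on a log axis, with Mettl3/14nKO in red, wild-type in dark blue, circles for replicate 1, triangles for replicate 2 and short lines for group means. Ins2 lay at 31327 and 32698 FPKM in Mettl3/14nKO and at 71944 and 82684 FPKM in wild-type libraries, while Ucn3 lay at 51.9 and 45.7 against 15.1 and 16.7 FPKM.

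Insulin transcripts fell in Mettl3/14nKO islets while the glucagon transcript Gcg did not pass in the filtered edgeR fit of all libraries. Ins2 (ENSMUSG00000000215, chromosome 7:142678656-142743381) changed by a log2 fold of -0.94 (SE 0.16, adjusted p = 0.00669) and Ins1 (ENSMUSG00000035804, chromosome 19:52264297-52265476) by -0.64 (SE 0.16, adjusted p = 0.0412). Both had lower FPKM in 2 of 2 Mettl3/14nKO libraries than in either wild-type library, with Ins1 at 8804 and 9143 against 16177 and 18022. The 2 insulin genes are close copies, so fragments may have been divided between them uncertainly. Iapp, which encodes the amyloid peptide co-secreted with insulin, fell by 0.95 (SE 0.17, adjusted p = 0.00741). The pancreatic polypeptide gene Ppy fell by 2.24 (SE 0.34, adjusted p = 0.00287), from 532 and 1501 FPKM in wild-type to 160 and 182, and its neighbour Pyy by 1.28 (adjusted p = 0.00325). Among other hormones, Sst had a log2 fold change of 0.04 and Ghrl of -0.49, and neither passed. Gcg stood at 0.41 (adjusted p = 0.248), but passed with edgeR without a filter on low counts (0.39, adjusted p = 0.00334). It stood at 0.60 without Mettl3/14nKO replicate 1 and at 0.57 without wild-type replicate 1. With limma, Ins1, Ins2, Iapp and Ppy had adjusted p of 0.262, 0.230, 0.193 and 0.147. With DESeq2, Ins1 (0.000111) and Ins2 (2.17e-10) passed, while Iapp (0.0657), Ppy (0.0911) and Pyy (0.0834) did not.

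Of 38 tested genes of beta-cell function and maturation, 1 rose and 6 fell with edgeR, and 3 rose and 10 fell when adjusted over the list alone (limma: 0 over all genes, 1 higher and 6 lower adjusted over the list alone). Ucn3 (ENSMUSG00000044988, chromosome 13:3940688-3945349) rose by a log2 fold of 1.88 (SE 0.18, adjusted p = 0.00019), with a limma adjusted p of 0.0841. Entpd3, an ectonucleotidase of the beta-cell surface, fell by 0.94 (adjusted p = 0.00529). Pcsk1, which cleaves proinsulin, fell by 0.81 (adjusted p = 0.0371), a call lost without Mettl3/14nKO replicate 1 (0.161) or wild-type replicate 2 (0.0851). The list as a whole was lower with camera (adjusted p = 0.0475, but adjusted p = 0.738 with an estimated correlation). Without Mettl3/14nKO replicate 1 its adjusted p was 0.370, without wild-type replicate 2 it was 0.197, 11 members fell without Mettl3/14nKO replicate 2, and 2 rose without wild-type replicate 1. Several genes central to beta-cell identity did not pass. The glucose transporter gene Slc2a2 had a log2 fold change of 0.29 (adjusted p = 0.575), Pdx1 of 0.11 (0.795), Nkx6-1 of -0.10 (0.782), Neurod1 of -0.38 (0.199) and Mafa of 0.56 (0.211). Neurod1 passed without Mettl3/14nKO replicate 2 (adjusted p = 0.0366) and Mafa without wild-type replicate 1 (0.00172).

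Other endocrine lists showed few called members. Of 27 islet transcription factors, 1 rose, Onecut2 (1.65, adjusted p = 0.00304), a gene named after its value was seen, and 0 fell, with 3 and 0 adjusted over the list alone (camera adjusted p = 0.374). The members that rose numbered 3 without Mettl3/14nKO replicate 1 and 2 without either wild-type replicate. Hnf4a and Irx1 had log2 fold changes of -0.58 and 1.11 and did not pass, although Irx1 passed without Mettl3/14nKO replicate 1 (adjusted p = 0.0310). Of 10 alpha-cell markers 0 passed (2 higher adjusted over the list alone, camera adjusted p = 0.330), and without Mettl3/14nKO replicate 1 the list had an adjusted p of 0.0373 and 3 members rose, against 1 without either wild-type replicate. Of 9 delta- and gamma-cell markers, Ppy and Pyy fell, also when adjusted over the list alone (camera adjusted p = 0.555; the edgeR median was 0.04, opposite in sign to the camera direction). Of 3 epsilon-cell markers 1 rose, Acsl1 (1.96, adjusted p = 0.00236), a fatty acid activating enzyme that many tissues use, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.964, upward against a median of -0.49). Of 15 endocrine progenitor genes 0 passed (1 higher adjusted over the list alone, camera adjusted p = 0.502), while 1 rose with edgeR without a filter on low counts. Of 27 genes of insulin granule exocytosis, 1 rose, Cacna1c (0.66, adjusted p = 0.0237), named after its value was seen, and 0 fell, with 2 higher and 4 lower adjusted over the list alone. Without a filter on low counts, 4 members fell with edgeR. That list was lower with camera at an adjusted p of 0.0327, against 0.333 on the fragments and adjusted p = 0.738 with an estimated correlation, and leaving out any 1 library ended its call (0.0619 to 0.134), while Cacna1c was not called without either wild-type replicate, when 0 members rose.

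Of 15 tested endothelial markers 8 fell in Mettl3/14nKO islets and 0 rose, 13 fell when adjusted over the list alone, and all 15 had negative log2 fold changes (median -1.22). With limma, 0 passed over all genes and 14 were lower adjusted over the list alone. Plvap (ENSMUSG00000034845, chromosome 8:71497765-71511752), which forms the diaphragms of fenestrated capillaries, fell by 2.93 (SE 0.25, adjusted p = 0.000144), from 33.2 and 34.8 FPKM in wild-type to 3.11 and 4.56. Eng, a TGF-beta co-receptor of vessels, fell by 1.63 (adjusted p = 0.000265), Emcn by 2.26 (0.00217) and the VEGF receptor gene Flt1 by 2.64 (0.0015). Camera gave an adjusted p of 4.86e-12 for the list and adjusted p = 0.738 with an estimated correlation. Summed over the list, endothelial markers took 543 and 352 CPM in Mettl3/14nKO and 1489 and 1210 in wild-type libraries.

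**Figure D2:**
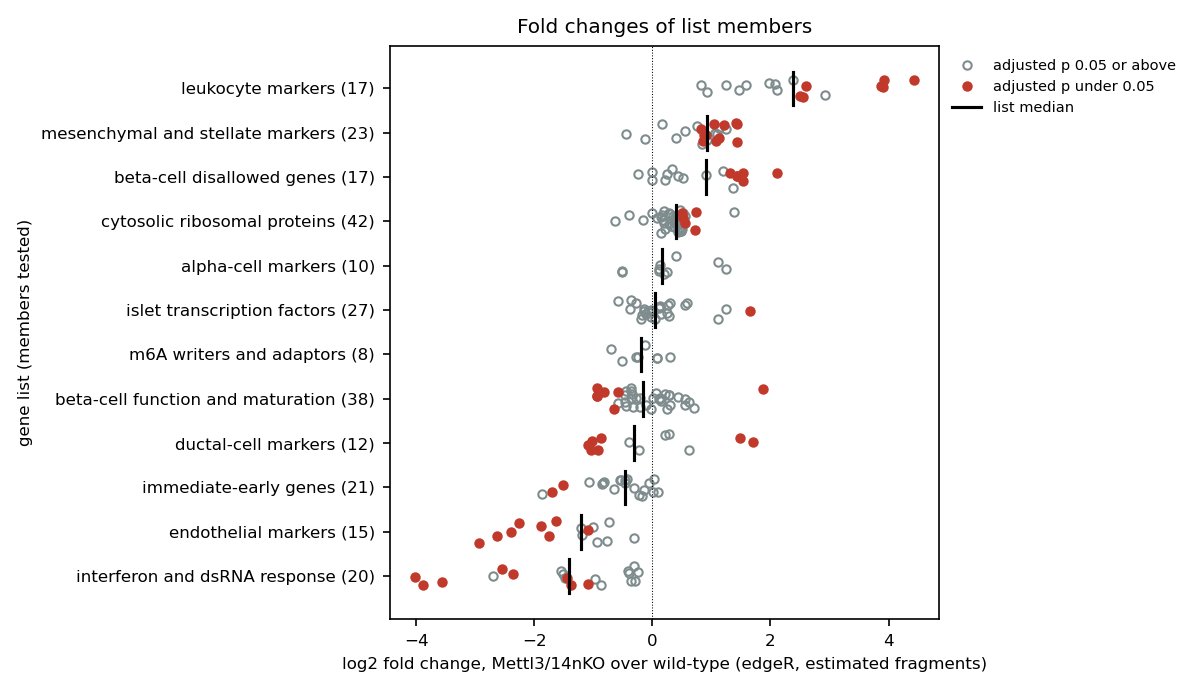
The edgeR log2 fold change, Mettl3/14nKO over wild-type, of each tested member of 12 gene lists; filled red circles passed an adjusted p of 0.05, open circles did not, and black bars mark list medians. The medians ran from 2.39 for leukocyte markers to -1.41 for the interferon and dsRNA response.

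Of 17 tested leukocyte markers 7 rose and 0 fell, 17 rose when adjusted over the list alone, and all 17 had positive edgeR log2 fold changes (median 2.39) (limma: 0 over all genes, 11 of 20 adjusted over the list alone). The complement genes C1qb and C1qc, made by macrophages, rose by 2.50 (adjusted p = 0.00581) and 3.90 (0.00444), and S100a8, a neutrophil calcium-binding protein gene, by 4.44 (0.00907), while Tyrobp stood at 1.59 (0.172). C1qc did not pass without Mettl3/14nKO replicate 1 (0.0843). With DESeq2, 1 of the markers passed, C1qc (0.0305). Camera gave an adjusted p of 3.3e-21 and adjusted p = 0.738 with an estimated correlation. Leukocyte markers summed to 456 and 778 CPM in Mettl3/14nKO and to 75.7 and 174 in wild-type libraries.

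Mesenchymal and stellate-cell transcripts, most of them collagens and other matrix genes, rose in 11 of 23 tested members and fell in 0, with 17 higher adjusted over the list alone (limma: 0 in both counts). Col1a1 rose by 1.41 (adjusted p = 0.00275), the fibronectin gene Fn1 by 1.43 (0.000872), Col1a2 by 1.21 (0.00178) and Col6a1 by 1.04 (0.00229). The list had a camera adjusted p of 2.44e-12 and adjusted p = 0.738 with an estimated correlation. The number of members that rose was 20 without wild-type replicate 1, 17 without Mettl3/14nKO replicate 2 and 6 without wild-type replicate 2 or with DESeq2. Summed markers took 15200 and 11010 CPM in Mettl3/14nKO and 7715 and 5318 in wild-type libraries. Of 17 genes normally kept low in beta cells (disallowed genes), 6 rose and 0 fell, with 8 higher adjusted over the list alone (limma: 0 and 3 higher). Camera gave 6.52e-06 for that list and adjusted p = 0.738 with an estimated correlation, and 3 members rose without Mettl3/14nKO replicate 1 and 3 with DESeq2. The members with the smallest limma p, given with their edgeR values, were the stromal chemokine gene Cxcl12 (2.12, adjusted p = 0.00121), the leukocyte-rich gene Arhgdib (1.54, 0.0199), Lmo4 (1.32, 0.0358) and Igfbp4 (1.44, 0.0053). Several of them are also expressed by the cell types whose markers were higher. Arhgdib did not pass without wild-type replicate 1 (0.0532), and Lmo4 did not pass without Mettl3/14nKO replicate 1 (0.194), wild-type replicate 1 (0.0552) or wild-type replicate 2 (0.125).

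**Figure D3:**
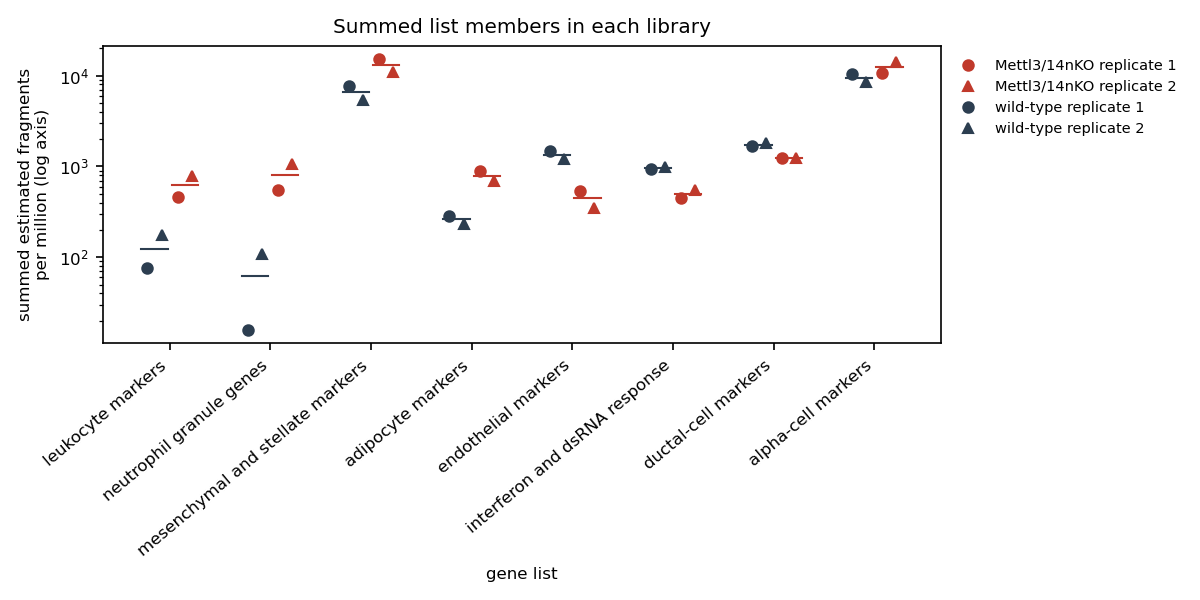
Summed CPM of the members of 8 gene lists in each library on a log axis, with Mettl3/14nKO in red, wild-type in dark blue, circles for replicate 1, triangles for replicate 2 and short lines for group means. Leukocyte markers lay at 456 and 778 in Mettl3/14nKO against 75.7 and 174 in wild-type libraries, and endothelial markers at 543 and 352 against 1489 and 1210.

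Of 20 tested genes of the interferon and double-stranded RNA response 8 fell and 0 rose, 14 fell when adjusted over the list alone, and all 20 had negative edgeR log2 fold changes (median -1.41) (limma: 0 over all genes, 14 adjusted over the list alone). The antiviral enzyme gene Rsad2 fell by 3.88 (SE 0.35, adjusted p = 0.000181), from 8.89 and 10.5 FPKM to 0.526 and 0.579. Ifit3 fell by 3.56 (0.00254) and Oasl2 by 1.38 (0.0208). Isg15, a ubiquitin-like protein gene, had 1 and 0 fragments in Mettl3/14nKO and 14 and 14 in wild-type libraries, a wild-type to Mettl3/14nKO ratio of 19.1 with a 95% counting interval of 3.16 to 781. Isg15 passed with edgeR (0.0317) but not when any 1 library was left out (0.114 to 0.251), and Oasl2 did not pass without Mettl3/14nKO replicate 1 (0.0843). Camera gave the list an adjusted p of 4.92e-10 and adjusted p = 0.738 with an estimated correlation. The number of members that fell was 2 with DESeq2 and 15 with edgeR without a filter on low counts. Fewer fell when Mettl3/14nKO replicate 1 or wild-type replicate 2 was left out. Endothelial markers, at 543 and 352 against 1489 and 1210 CPM, moved in the same direction.

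Of 28 genes of ER stress and the unfolded protein response, 3 fell and 1 rose, with 8 lower and 1 higher adjusted over the list alone (limma: 0 over all genes, 8 lower adjusted over the list alone). Those that fell were the asparagine synthetase gene Asns (-1.36, adjusted p = 0.00345), the glutathione-degrading enzyme gene Chac1 (-1.28, 0.0193) and Ern1 (-0.62, 0.0259), while the chaperone gene Calr rose (0.62, 0.0120), Ern1 and Calr being named after their values were seen. The list was lower with camera (adjusted p = 0.0217, but adjusted p = 0.738 with an estimated correlation). Without Mettl3/14nKO replicate 1 its adjusted p was 0.0794, Chac1 had 0.0926 and 1 member fell, without wild-type replicate 2 the list had 0.197, and without wild-type replicate 1 no member rose. With median-ratio rescaling the list had 0.138. Of 21 immediate-early genes, Dusp1 (-1.52, adjusted p = 0.0282) and Nr4a1 (-1.69, 0.0321) fell, 2 also when adjusted over the list alone (limma: 0 and 8 lower). That list had a camera adjusted p of 0.000203 and adjusted p = 0.738 with an estimated correlation. Dusp1 did not pass without Mettl3/14nKO replicate 1 (0.162) or wild-type replicate 1 (0.0605), nor did Nr4a1 (0.0624 and 0.161). Of 42 cytosolic ribosomal protein genes 5 rose (Rps24, Rpl11, Rplp1, Rpl4 and Rpl19, by 0.50 to 0.73, named after their values were seen) and 0 fell, with 18 higher adjusted over the list alone. Camera gave this list 0.000536, adjusted p = 0.738 with an estimated correlation, 0.487 without Mettl3/14nKO replicate 1 and 0.175 without wild-type replicate 1. The members that rose numbered 14 without Mettl3/14nKO replicate 2, 2 without Mettl3/14nKO replicate 1, 3 without wild-type replicate 2 and 1 with DESeq2, and without wild-type replicate 1, 1 member fell.

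Markers of further cell types differed in part. Of 12 ductal-cell markers 2 rose and 5 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.330, 0.0191 on the fragments). The members that rose numbered 1 without Mettl3/14nKO replicate 2 or wild-type replicate 2. Spp1, a secreted phosphoprotein gene also active in macrophages, rose by 1.71 (adjusted p = 0.000302), and the epithelial genes Krt8, Krt18 and Epcam fell by 1.10 (0.000881), 0.92 (0.00274) and 1.04 (0.00649). Of 12 Schwann-cell and neuronal markers 2 rose and 2 fell, with 2 and 4 adjusted over the list alone (camera adjusted p = 0.374). The neuronal genes Stmn2 and Prph fell by 2.07 (0.00199) and 2.45 (0.00466), and the glial gene Cdh19 rose (25 against 3 fragments, ratio 12.2 with a counting interval of 3.73 to 63.2), a gene named after its values were seen. Without Mettl3/14nKO replicate 2 or wild-type replicate 2, 0 of these markers rose, without wild-type replicate 1 it was 1, and without Mettl3/14nKO replicate 2 the list was lower with camera (0.0399), as with a mean FPKM filter of 5 (0.00087). Of 3 erythroid markers 1 fell, the haemoglobin gene Hba-a1 (-1.96, 0.00716), with 2 lower adjusted over the list alone (camera adjusted p = 0.0105, 0.398 without a filter and adjusted p = 0.738 with an estimated correlation). The members that fell numbered 2 without Mettl3/14nKO replicate 2 or wild-type replicate 1. Haemoglobin genes are near-identical copies, so single members are uncertain. Of 3 liver and gut markers 1 fell, Vil1 (-1.39, 0.0131), with 2 lower adjusted over the list alone (camera adjusted p = 0.330). Of 4 acinar markers 0 passed, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.330). Without a filter on low counts, 1 acinar marker fell with edgeR.

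Growth, energy and lipid genes showed few calls. Among 34 proliferation genes, 20 glycolysis genes, 20 cholesterol synthesis genes and 45 nuclear-encoded genes of oxidative phosphorylation, 0 passed with limma or edgeR, over all genes or adjusted over the list alone. Their camera adjusted p were 0.719, 0.994 (upward, against an edgeR median of -0.01), 0.828 and 0.0178. Without wild-type replicate 1, 1 proliferation gene rose. The oxidative phosphorylation list was lower as a whole only on FPKM, with 0.644 on the fragments, adjusted p = 0.738 with an estimated correlation, and 0.0556, 0.0585 and 0.363 without Mettl3/14nKO replicate 1, Mettl3/14nKO replicate 2 and wild-type replicate 2. Of 9 mitochondrially encoded genes 1 rose, mt-Nd6 (0.73, adjusted p = 0.0172, and 0.141 without wild-type replicate 2), with 6 higher adjusted over the list alone (camera adjusted p = 0.0658, 7.75e-05 on the fragments and 0.0235 without Mettl3/14nKO replicate 1). The members that rose numbered 3 without Mettl3/14nKO replicate 1 or wild-type replicate 1. Of 21 p53 targets and apoptosis genes 1 rose, Ccng1 (0.65, adjusted p = 0.0483), named after its value was seen, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.606), and 0 rose without Mettl3/14nKO replicate 2 or wild-type replicate 1. Of 11 growth-hormone and prolactin targets 1 rose, the growth factor gene Igf1 (2.40, adjusted p = 0.00649), also adjusted over the list alone (camera adjusted p = 0.452, upward against a median of -0.05).

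The genes nearest to the limma threshold, none of which passed it (adjusted p 0.0709 to 0.0841), belonged to some of the same groups. Higher in Mettl3/14nKO were the neutrophil granule genes Camp (10 and 19 fragments against 0 and 0) and Ngp (90 and 149 against 0 and 7), the peptidoglycan receptor gene Pglyrp1 (10 and 9 against 1 and 0, ratio 27.8 with a counting interval of 4.43 to 1157) and the stefin genes Stfa2 (12 and 11 against 1 and 2, ratio 11.2, 3.39 to 58.5) and Stfa2l1 (5 and 15 against 0 and 0). Intervals cover counting error only. Stefin genes are near-identical copies, so their single values are uncertain. Further genes were Ifitm1 (edgeR 3.89, adjusted p = 0.00275), Serpinf1 (2.66, 0.000265), the NAD synthesis gene Nmnat1 (2.90, 0.000928), the matrix protease gene Mmp7 (11 and 12 fragments against 0 and 0) and Ucn3. Stfa2 did not pass with edgeR without Mettl3/14nKO replicate 2, wild-type replicate 1 or wild-type replicate 2 (0.129 to 0.146), nor did Pglyrp1 without wild-type replicate 1 (0.0586) or wild-type replicate 2 (0.234). Lower in Mettl3/14nKO, besides Plvap, Eng, Emcn, Rsad2, Isg15 and Stmn2, were Arhgap36 (ENSMUSG00000036198, chromosome X:49463945-49500244), a regulator of hedgehog signalling, Prodh2, Efcab4a and Mettl23. Arhgap36 fell by 2.46 (SE 0.17, adjusted p = 1.7e-05), from 35.0 and 39.5 FPKM to 6.57 and 4.91 FPKM. Prodh2, a hydroxyproline dehydrogenase gene, had 0 and 0 against 30 and 20 fragments (edgeR adjusted p = 0.00643), and Efcab4a 0 and 0 against 6 and 10. Mettl23 did not pass with edgeR (-1.42, 0.223).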

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

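Limma on the genes edgeR tests, limma on CPM, edgeR and its alternatives were chosen after seeing the data. The limma counts of 0 higher and 0 lower genes became 1 and 2 with a mean FPKM filter of 5, 16 and 15 at an adjusted p of 0.10, 7 and 7 on the genes edgeR tests, 153 and 125 on log2(CPM + 1), 92 and 50 with DESeq2 and 230 and 176 with edgeR. Leaving out 1 library gave 0 to 11 higher, the 11 without wild-type replicate 2, and 0 lower. With the replicate number as a block they were 114 and 236. Same-numbered libraries hardly deviated together (correlation 0.015 in FPKM and 0.026 in fragments). The labels do not say whether equal numbers pair libraries, and these correlations do not settle it. The other settings kept 0 and 0. The edgeR counts became 469 and 388 without a filter and 92 and 50 with DESeq2, and leaving out 1 library gave 178 to 345 higher and 120 to 249 lower. The beta-cell function and maturation list (adjusted p = 0.0475) had 0.0568 at a pseudocount of 0.01, 0.0812 without a filter, 0.165 with median-ratio rescaling, 0.145 with quantile normalization, 0.217 with the block, 0.188 without a trend, 0.738 with an estimated correlation, 0.0619 with edgeR, 0.105 on log2(CPM + 1), 0.228 and 0.114 on edgeR's genes with and without rescaling, and 0.0306 to 0.370 with 1 library left out. The block also ended the edgeR calls of Ins1 (0.0520) and Lmo4 (0.0524). The cause of these changes was not tested, except that a higher threshold admits more genes. 0 called results reversed. Of all values of named genes, 44 lost and 41 gained a call with edgeR and 239 gained one with limma; of all list values, 55 lost and 14 gained one. Signs of uncalled values changed 15 times with limma, 15 with edgeR and 26 among lists. The endothelial, leukocyte, mesenchymal, interferon, disallowed and immediate-early lists kept their direction and passed in every setting with a preset correlation (highest adjusted p 5.66e-09, 5.15e-11, 0.000174, 3.74e-05, 0.0104 and 0.00743). Of lists whose call changed, adjusted p with a preset correlation ran from 0.0136 to 0.348 for insulin granule exocytosis, 0.00634 to 0.197 for ER stress, 0.000613 to 0.658 for oxidative phosphorylation, 4.72e-05 to 0.550 for mitochondrially encoded genes, 5.48e-12 to 0.487 for ribosomal proteins, 1.56e-06 to 0.398 for erythroid, 0.00087 to 0.806 for Schwann-cell and neuronal, 0.00694 to 0.915 for acinar, 0.0373 to 0.781 for alpha-cell and 0.0191 to 0.527 for ductal-cell markers. Depth limits low genes most, since a library held 744008 to 1617415 fragments.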

Other observations

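The 4 gene lists added here, the pathways and the tests of FPKM spread, scaling, endocrine share, blood, adipose tissue, beta-cell number and dilution were chosen after the results were seen. The test on haemoglobin was narrowed after its first form was seen, and so was the reading of the sequence tests. Genes of serine and one-carbon metabolism and the amino-acid response fell in 14 of 29 tested members and rose in 0 (median -0.68, edgeR). Phgdh, the first enzyme of serine synthesis, fell by 1.74 (adjusted p = 0.00437), Psat1 by 1.19 (0.00649), the mitochondrial folate enzyme genes Shmt2 and Mthfd2 by 1.26 (0.00442) and 1.23 (0.00254). Adipocyte markers rose in 4 of 9 and fell in 0. Among them were the lipid carrier gene Fabp4 (2.89, 0.00274) and the lipoprotein lipase gene Lpl (1.55, 0.00019). Car3 had 164 and 24 fragments against 0 and 0. Members that did not pass included Pparg (0.31, adjusted p = 0.867), Dgat2 (0.18, 0.913), Lipe (0.46, 0.701), Pnpla2 (0.66, 0.214) and Cd36 (0.94, 0.462). Plin1 (29 and 5 fragments against 0 and 0, DESeq2 adjusted p = 0.0161) and Adipoq (9 and 4 against 0 and 0, DESeq2 adjusted p = 0.320) were too low to be tested with edgeR. Neutrophil granule genes rose in 9 of 11 and fell in 0 (median 3.92, or 3.83 with genes absent from 1 group at a floor of 3 counts over that group's libraries together). Each of these 3 lists had an adjusted p of 0.0579 with an estimated correlation, over the 4 added lists. Their genes were picked knowing the values, so their directions are not independent evidence.

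The smallest edgeR adjusted p belonged to the apolipoprotein gene Apoe, which rose by 2.65 (adjusted p = 9.9e-06), from 22.1 and 46.8 to 221 and 161 FPKM, and the MHC class I light chain gene B2m rose by 1.21 (0.000766). Of 272 annotated pathways with at least 10 tested genes, 10 passed with camera on FPKM, 8 higher and 2 lower, and 0 with an estimated correlation (0.999 or more).

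Limma called 0 genes on FPKM and edgeR 406 on fragments. Scaling between libraries as the cause is argued against by rescaled FPKM of the genes edgeR tests, which gave 0 limma calls. Larger spread in FPKM may contribute, since the median residual SD of log2(FPKM + 1) was 1.22 times that of log2(CPM + 1), above the bound of 1.2 set for this cause, but with FPKM centred by library the ratio was 1.07, between the bounds, so the question stays open. Uneven FPKM per fragment may also contribute, since FPKM rebuilt with 1 value per fragment and gene gave 65 limma calls against 14 from the deposited FPKM of the same genes, between the bounds set for that test. Limma on log2(CPM + 1) called more, 153 higher and 125 lower. Even FPKM per fragment therefore did not close the gap. The real split of the 4 libraries was 1 of 3 with as many edgeR calls (406, the highest other 0), and 3 splits are too few for a share under 0.05.

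Leukocyte and mesenchymal markers were higher while endothelial markers were lower. A lower share of endocrine cells as the whole cause would raise all 3, against which stands the endothelial median of -1.22 (bootstrap interval -1.89 to -1.004). That interval covers the spread among the list's genes, not between libraries. More blood would raise haemoglobin with the leukocyte markers, but haemoglobin stood at 33.7 and 60.5 CPM in Mettl3/14nKO and at 107 and 195 in wild-type libraries. Its log2 ratio had an upper counting limit of -0.33 while the leukocyte ratio was at least 1.39. That limit leaves out the spread between libraries, and haemoglobin also varied within each group. The first form, the whole erythroid list, gave a highest ratio of -0.14, within counting error. Haemoglobin was thus not higher in these Mettl3/14nKO libraries, but the test does not decide whether blood differed between the genotypes. Carried-over adipose or connective tissue and an effect of genotype on these cells both stay open, because the adipocyte list was picked knowing its values, so that its sum, at least 2.39 times as high in any Mettl3/14nKO as in any wild-type library and mostly Lpl (586 and 310 against 215 and 220 fragments), does not bear on it (5 of the 20 genes had at least 10 fragments in both wild-type libraries, and 1 stands in another list).

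Insulin transcripts fell while Gcg did not pass in the filtered edgeR fit of all libraries. Fewer beta cells as the whole cause would lower other beta-cell genes about as much as Ins1 (-0.64). The 19 other beta-cell-enriched genes, all also in other lists, had a median log2 fold change of 0.14 (bootstrap interval -0.21 to 0.55). Of them 1 rose and 1 fell. That set was drawn up after the results were seen, with Ucn3, which rose, and without Pcsk1, which fell. It therefore does not decide the question. Bootstrap intervals in this paragraph cover the spread among genes, not between libraries. With Ins1, Ins2, Gcg and Lars2 left out of the library totals, Ins2 stayed at -0.93 (SE 0.16). Each of these genes took at most 4.01% of a library's fragments, so leaving them out could hardly have moved that value. The test therefore cannot decide whether abundant genes set the scale. Islet cells diluted by other tissue as the whole cause would also lower the other beta-cell genes about as much as Ins1. The 35 genes of the beta-cell function and maturation list other than Ins1, Ins2 and Iapp had a median log2 fold change of -0.0197 (bootstrap interval -0.35 to 0.14). Of them 1 rose and 3 fell. In these libraries their median thus fell less than Ins1. This comparison was set up after the results were seen and shares genes with the set above. Its interval leaves out the error of Ins1 and the spread between libraries, so it does not decide on dilution. An effect of genotype stays open, untested.

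Transcripts with more GGACT, a core m6A motif, showed no larger rise in a rank correlation across genes. Methylation was not measured, so methylated transcripts were not compared with others. Across 10443 genes, which are not independent replicates, the partial rank correlation of motif density with the log2 fold change, given mRNA length, GC content and level, was -0.0198. For the longest internal exon it was 0.0352 across 9773 genes, above that of any difference between replicates (0.0221) but below the bound of 0.05, which its interval reaches. Before an interval was added this was read as an absence, and neither presence nor absence of such a relation is shown.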
